A study of Caenorhabditis elegans with 2 samples.

How the data were processed

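The measurements were ChIP-seq profiles of UNC-120, a muscle transcription factor of the SRF type of MADS box proteins, in Caenorhabditis elegans. Per the labels, worms of strain OP659 carried UNC-120 fused at its C terminus to GFP and FLAG, and chromatin was precipitated with an antibody against GFP. Whole embryos of mixed stage and mixed sex were collected 3 h after synchronization by bleaching, and chromatin was broken by sonication. The 2 libraries were labelled biological replicates 1 and 2 of 1 group. The labels name a possible control experiment, and its data were not used here.

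The deposited files were lists of regions in narrowPeak format, made by the authors in genome builds ce10 and ce11. Per the listing deposited with the samples, each build had a ranked list of peaks and background for each replicate, a ranked list for both replicates pooled, and an optimal list of regions that passed a threshold on the irreproducible discovery rate (IDR). Column 7 of these files holds a score of peak strength that the authors' peak caller gave to each region. Its scale is not given in the sources used here, so it served mainly to describe, rank and filter regions within a list. Between lists, scores were only correlated across replicates and described as a ratio between builds. Column 9 is, by the definition of the deposited format, the -log10 of a q-value, and it was not used in any test. The aligner, the peak caller and their versions are not given in the sources used here. No list holds read counts, so the depth of the libraries is unknown and no value below carries a counting interval for reads.

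Only the ce11 lists were set against a genome, the WBcel235 assembly, which is the same sequence as ce11, with gene models of Ensembl release 115. No region ended beyond its chromosome, and coordinates were not converted between builds; they are given counted from 1. The 5 mitochondrial regions of the ce11 IDR list were set aside, which left 2946 nuclear peaks. A protein-coding gene was called bound when a peak summit lay between 1000 bp upstream and 500 bp downstream of an annotated transcript 5' end, and a summit could be given to several genes. Ranks count nuclear regions by descending score, and a peak took its rank in a replicate from the nearest summit of that replicate's list within 200 bp, so that neighbouring summits can share a rank.

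The gene lists, windows, tests and alternatives were fixed before the data were examined. Members of 10 lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 10 lists. Short sequences within 100 bp of each summit were compared with a window of the same size 750 bp away, on a side drawn at random, by two-sided exact McNemar tests; 6 sequences besides the CArG box were adjusted together. Windows drawn from promoters and matched on GC content served as an alternative control. The numbers of windows with each sequence were then compared by two-sided Fisher's exact tests. The order of the score was compared with CArG presence by 100000 permutations. Summit locations were compared with 10000 circular shifts of the summits within each chromosome, and the share of peaks on X with its share of protein-coding genes by an exact binomial test. Peaks and genes are not biological replicates, so these p-values describe the peak list and not variation between worm cultures. Shares carry Wilson 95% confidence intervals. The 95% intervals of ratios between summit and control windows treat the windows as independent, although the McNemar tests are paired.

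Genes named in the text followed a fixed rule. It took unc-120, hlh-1, hnd-1 and unc-119, the genes assigned to the 10 strongest regions of the IDR list, up to 4 bound members of each list with the highest scores, and up to 2 unbound members, first by name, of each of 4 body wall muscle lists. All list members were found in the annotation. Other genes named below were chosen after their values were seen.

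The alternatives changed the window that makes a gene bound, the control windows, the motif window, the promoter length, the overlap rule and the peak threshold, or used the 2946 top regions of a replicate alone. Keeping 1 summit per 400 bp, and leaving out peaks within 200 bp of tRNA and snoRNA genes, were added after seeing the data. The functions were tested on simulated peaks: 100% of genes given a peak in their window were called bound, 3% of random lists had an unadjusted p below 0.05, and a CArG box written into 10.5% of windows was measured as an excess of 10.4 percentage points. Summits in that motif check were placed at random. It therefore did not test the effect of the GC difference between real summit and control windows (45.6% and 35.7%), or the detection of a smaller excess. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.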

Results

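Binding of UNC-120, a transcription factor that acts with the MyoD homologue HLH-1 in body wall muscle development, was mapped by anti-GFP ChIP-seq in whole C. elegans embryos that expressed an UNC-120-GFP fusion. The data comprised 2 biological replicates of 1 group, without a second condition, so the comparisons below set bound against unbound genes and peak summits against other sequence. The authors' ce11 IDR list held 2951 regions with a median width of 444 bp, of which 2946 were nuclear. These were assigned to 1849 of 19973 protein-coding genes, or 9.26%. For 1359 of the nuclear peaks, no 5' end of a protein-coding gene was within the assignment window.

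The first comparison asked whether genes of body wall muscle were bound more often than other genes. Of 26 genes for the sarcomere, the contractile unit of muscle, 21 were bound (80.8%, Wilson 95% interval 62.1 to 91.5), against 9.16% of other genes, an odds ratio of 41.6 (Fisher's exact test, adjusted p = 3.71e-17). The myosin heavy chain gene unc-54 had the strongest sarcomere peak, 133 bp upstream of its 5' end, with a score of 1443 and rank 8 among nuclear peaks. The myosin light chain gene mlc-2 followed with a score of 881, the troponin I gene unc-27 with 846 and the twitchin gene unc-22 with 801. Bound members had a median score of 541, against 301 for all bound genes. The other troponin I genes tni-1 and tni-3 were not bound, nor were unc-45, unc-78 and unc-87. With a window from 500 bp upstream to 100 bp downstream, 17 sarcomere genes were bound, an odds ratio of 26.5.

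Genes that anchor muscle filaments to the membrane and basement membrane were also bound more often, 15 of 22 (68.2%, 47.3 to 83.6; odds ratio 21.2, Fisher's exact test, adjusted p = 9.04e-11). The kindlin gene unc-112 had a peak 462 bp upstream with a score of 1240 and rank 15, and the LIM domain gene lim-9 a peak 71 bp upstream of an annotated 5' end with a score of 984. Scores were 540 at dim-1 and 511 at the type IV collagen gene let-2. The vinculin gene deb-1 and alp-1 were not bound. The odds ratio of this list was 33.7 without replicate 1, 14.7 without replicate 2 and 11.3 among the 1473 strongest peaks. It was 9.65 with the window from 500 bp upstream to 100 bp downstream and 34 with a window from 3000 bp upstream to the gene end.

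Genes for membrane excitation and calcium handling were bound in 10 of 22 cases (45.5%, 26.9 to 65.3; odds ratio 8.21, Fisher's exact test, adjusted p = 2.57e-05). Their strongest scores were lower than those of the sarcomere list, at 479 for the calcium channel subunit gene unc-36, 379 for the syntrophin gene stn-1, 376 for the junctophilin gene jph-1 and 359 for the calsequestrin gene csq-1. The acetylcholine receptor gene acr-16 and the calcium channel subunit gene ccb-1 were not bound. The count depended on the window: 20 of 22 were bound from 3000 bp upstream to the gene end (odds ratio 53.7), and 19 of 22 when each summit went to the nearest 5' end within 2000 bp (odds ratio 60.2). Against random lists matched on upstream intergenic length and number of 5' ends, the sarcomere list was bound in 21 cases where 2.78 were drawn on average, with an adjusted permutation p of 0.000667, the smallest these lists gave.

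**Figure D1:**
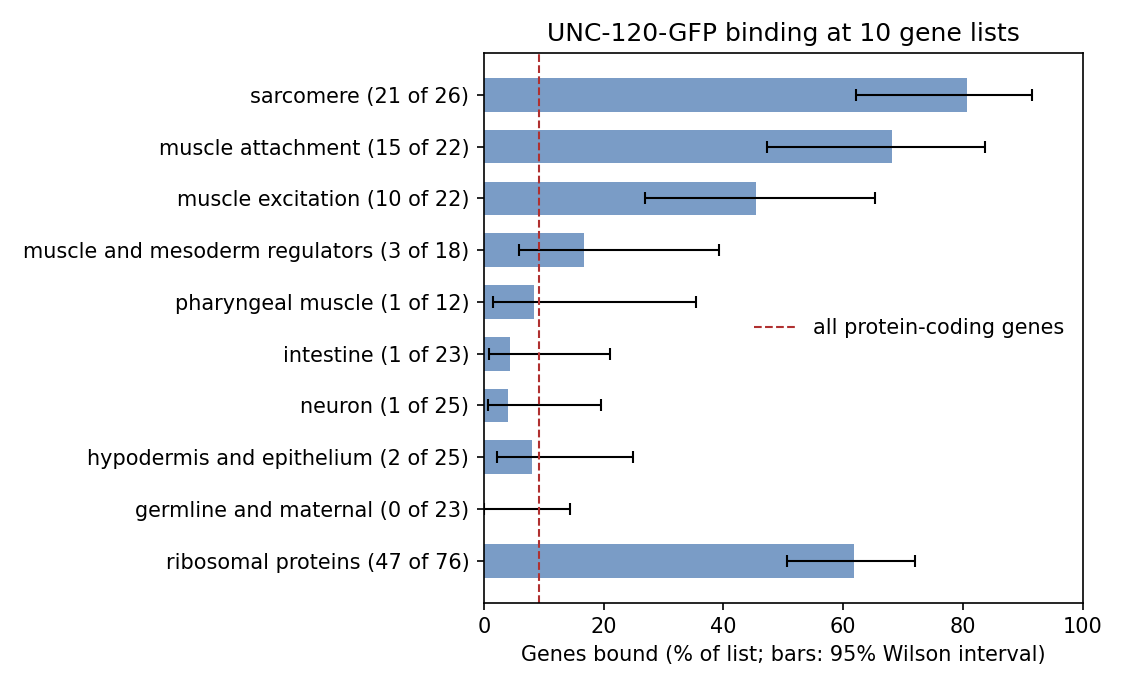
Share of genes bound in each of 10 gene lists, in percent, with 95% Wilson intervals; the dashed line marks the share of all protein-coding genes, 9.26%. The sarcomere list stands at 80.8% and the ribosomal protein list at 61.8%, while 0 of 23 germline and maternal genes were bound.

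Binding at genes of other tissues gave the reference for the muscle lists. The lists were not matched on transcription in these embryos, which was not measured here. Low shares in the reference lists therefore do not separate tissue from transcription. Of 23 intestine genes 1 was bound, the ezrin-type gene erm-1 with a score of 422 (4.35%, 0.772 to 21). Of 25 neuron genes 1 was bound, the synaptobrevin gene snb-1 with a score of 474 (4%, 0.71 to 19.5). The hypodermis and epithelium list had 2 of 25 bound, the spectraplakin gene vab-10 and the junction gene ajm-1, and the pharyngeal muscle list had 1 of 12, the T-box gene tbx-2 with a score of 194. None of the 23 germline and maternal genes was bound; a count of 0 allows a share of up to 13.0%, taken as 3 counts of the total, and the Wilson upper limit is 14.3%. These 5 lists did not differ from other genes by Fisher's exact test (adjusted p from 0.442 to 1), and their sizes leave wide intervals.

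Ribosomal protein genes, fixed as a ubiquitous reference, were bound in 47 of 76 cases (61.8%, 50.6 to 71.9; odds ratio 16.3, Fisher's exact test, adjusted p = 8.73e-29). The strongest peak lay 254 bp upstream of rpl-3, with a score of 1136 and rank 26. The next were rpl-35 with a score of 758, rpl-15 with 717 and rpl-23 with 646. Bound members had a median score of 353. When each summit went only to the nearest 5' end within 2000 bp, 28 of 76 were bound, an odds ratio of 5.55, and among the 1473 strongest peaks 27 of 76 were bound.

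The regulators of muscle and mesoderm fate included UNC-120's own gene and those it is known to act with. As a list they were bound in 3 of 18 cases (16.7%, 5.84 to 39.2; odds ratio 1.96, Fisher's exact test, adjusted p = 0.442), and without replicate 1 in 1 of 18. The genes lost were unc-120 and mef-2. For unc-120 the loss turned on the 1000 bp edge of the window, not on a missing peak. Its summits 912 and 1114 bp upstream took the same rank, 98, in replicate 2. The MyoD homologue hlh-1, on chromosome II from 4518574 to 4522528 (ce11), had a summit at 4518496, 78 bp upstream, with a score of 1300, and ranks of 10 and 15 in replicates 1 and 2. A further 4 summits at hlh-1 lay 2088 bp upstream and 135, 1606 and 1807 bp downstream of the gene's start, the last 2 of these in an intron. The homologue of vertebrate MEF2, mef-2, had a score of 216, and its rank in replicate 2 was 3155, below the 2946 top regions. The bHLH gene hnd-1 was not bound, nor were the homeobox genes ceh-24 and ceh-34.

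At unc-120 itself, on chromosome I from 8460225 to 8463015 (ce11), the list held 4 summits. The strongest lay in an intron at 8461349, 1124 bp downstream of the start, with a score of 941 and ranks of 55 and 80 in replicates 1 and 2. The others lay 912, 1114 and 2957 bp upstream, with scores of 453, 880 and 315. At unc-119, the gene mutated in this strain per the labels, a summit at 10906492 on chromosome III lay in a coding exon with a score of 355. A second in an intron at 10905368 had a score of 189. The strain carries transgenic unc-120 sequence, with unc-119 as the rescue marker of the transgene. Whether transgene DNA adds signal at these loci was not tested, and the count of unc-120 as a bound regulator carries the same limit.

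**Figure D2:**
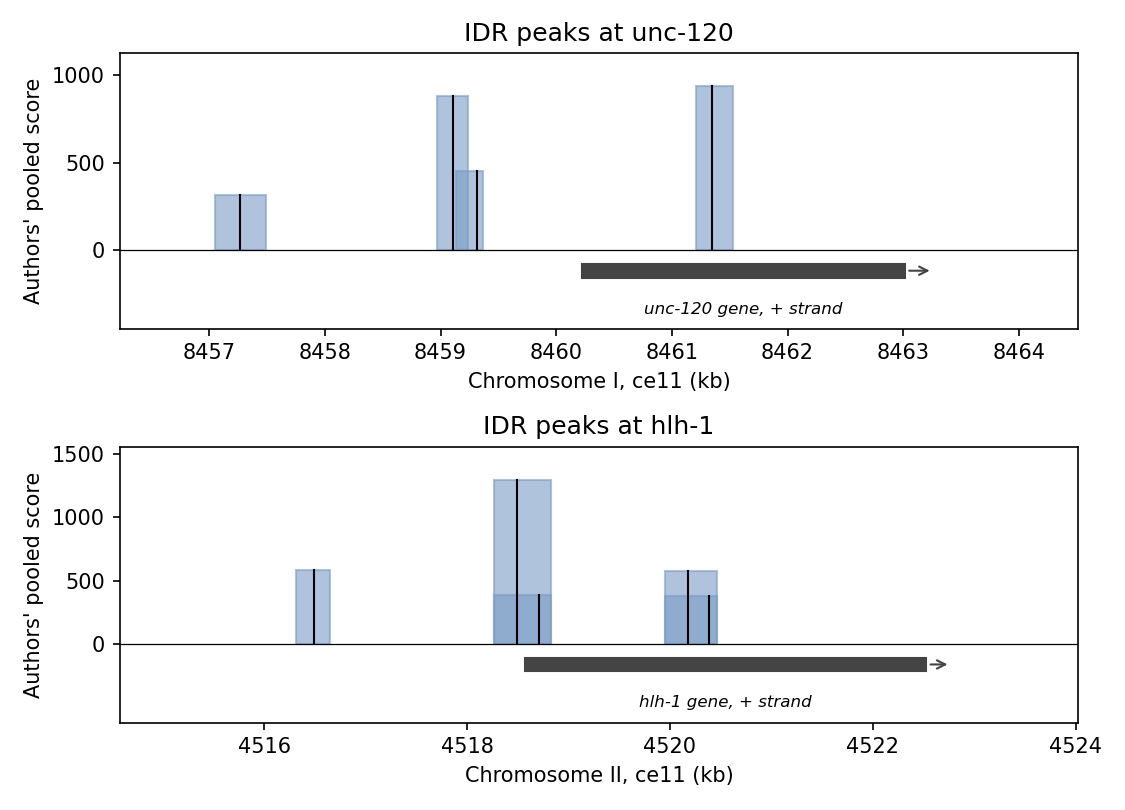
Authors' pooled score (vertical axis) of IDR peaks along the unc-120 and hlh-1 loci in ce11 (horizontal axis, kb). Boxes span each peak, black lines mark summits and dark bars the genes; the intronic unc-120 peak reaches 941 and the peak at the hlh-1 start 1300.

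The strongest nuclear peak, with a score of 2614, had rank 1 in both replicates and lay on chromosome I from 1873708 to 1874226, 34 bp upstream of tub-2 and 136 bp upstream of Y71G12A.5. Other genes assigned to the 10 strongest regions were the nuclear receptor gene nhr-40 with a score of 1521, the 14-3-3 gene ftt-2 with 1485, and unc-54. Another 4 of these regions had no protein-coding 5' end in the window. They included an intergenic region on chromosome III with its summit at 13062571 and a score of 1913, and an intron of K01F9.2 with its summit at 8874410 and a score of 1842.

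The genomic location of summits was compared with that of shifted summits. Promoters, taken as 1000 bp upstream of a 5' end, held 50.3% of summits against 21.8% ± 0.811 (SD over 10000 shifts), a ratio of 2.31. Coding exons held 1.05% against 20.9% ± 0.813, introns 17.8% against 28.8% ± 0.933 and 3' UTRs 0.373% against 2.43% ± 0.291. Noncoding genes held 5.50% against 3.17% ± 0.359. Each summit was given only 1 class, so this share leaves out summits at noncoding genes that were counted under another class. These 5 classes had an adjusted permutation p of 0.00028, the smallest the shifts could give. The 5' UTR share of 1.56% against 1.09% had an adjusted permutation p of 0.0345 and lost it among the 1473 strongest peaks (ratio 1.24, adjusted p = 0.469). Intergenic sequence held 23.4% against 21.8% (adjusted permutation p = 0.063). This excess passed the threshold without replicate 1 (adjusted permutation p = 0.0306) and with a 500 bp promoter (adjusted permutation p = 0.000467). The shorter promoter moves summits from 500 to 1000 bp upstream into other classes, and intergenic summits rose from 688 to 884.

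**Figure D3:**
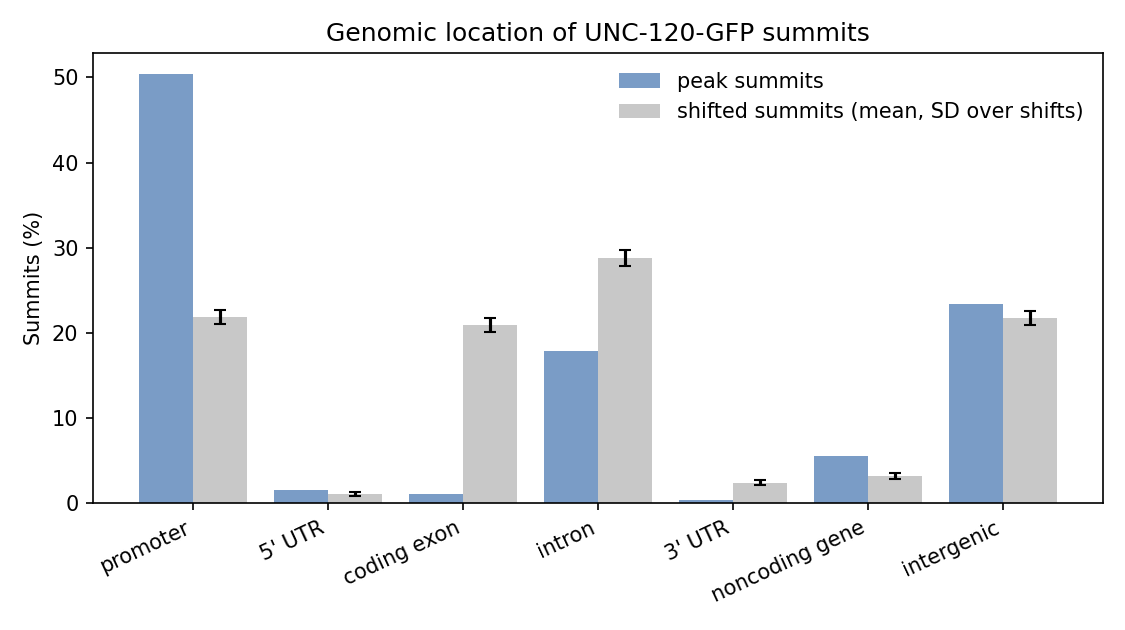
Percent of summits (vertical axis) in each of 7 annotation classes, for the 2946 nuclear peaks and for circularly shifted summits (mean, with SD over shifts as error bars). Promoters hold 50.3% of summits and coding exons 1.05%.

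The CArG box, CC(A/T)6GG, is the site of the SRF family, and was looked for within 100 bp of each summit. It was present at 43 of 2946 summits (1.46%, Wilson 95% interval 1.09 to 1.96) and in 34 control windows (1.15%), a ratio of 1.26 (0.809 to 1.98; exact McNemar test, p = 0.356). The result depended on the control and the peaks used. Against promoter windows matched on GC content, of which 0.713% had a CArG box, the ratio was 2.05 (Fisher's exact test, p = 0.00781). Against control windows it was 1.89 without replicate 2 (exact McNemar test, p = 0.00728). Among the 1473 strongest peaks it was 0.727 (exact McNemar test, p = 0.418). Summit windows had a mean GC content of 45.6% and control windows 35.7%. CArG presence had a Spearman's rho of -0.0392 with the score across peaks (permutation p = 0.0328; adjusted p = 0.0766 over 7 sequences), and -0.0255 with the lower of the replicate scores (permutation p = 0.167).

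Other short sequences, most of them sites of other factors, were compared in the same way. No factor was identified here for the repeat GAGAGAGA. The E-box CAGCTG was present at 9.40% of summits and 4.21% of control windows, a ratio of 2.23 (1.82 to 2.74; exact McNemar test, adjusted p = 3.52e-15), and 1.26 against GC-matched promoters. GAGAGAGA was present at 16.3% of summits and 1.87% of control windows, a ratio of 8.71 (6.62 to 11.5; exact McNemar test, adjusted p = 8.68e-91), and 5.21 against GC-matched promoters. The E-box CACCTG had a ratio of 1.32 (exact McNemar test, adjusted p = 0.0108), which turned to 0.746 against GC-matched promoters (Fisher's exact test, adjusted p = 0.00295). Its excess missed the threshold with 50 bp windows (exact McNemar test, adjusted p = 0.283) and among the 1473 strongest peaks (exact McNemar test, adjusted p = 0.238). The GATA site TGATAA was rarer at summits, at 10.6% against 17.7% (ratio 0.6, exact McNemar test, adjusted p = 4.43e-15), and stood at 0.994 against GC-matched promoters. A CArG box with 1 mismatch was rarer, at 16.4% against 22.3% (ratio 0.736, exact McNemar test, adjusted p = 2.93e-08). The MEF2 type site was found at 14 summits and in 23 control windows (exact McNemar test, adjusted p = 0.188). Its lower frequency at summits passed the threshold with 200 bp windows (ratio 0.51, exact McNemar test, adjusted p = 0.0085) and without replicate 1 (ratio 0.458, adjusted p = 0.041).

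**Figure D4:**
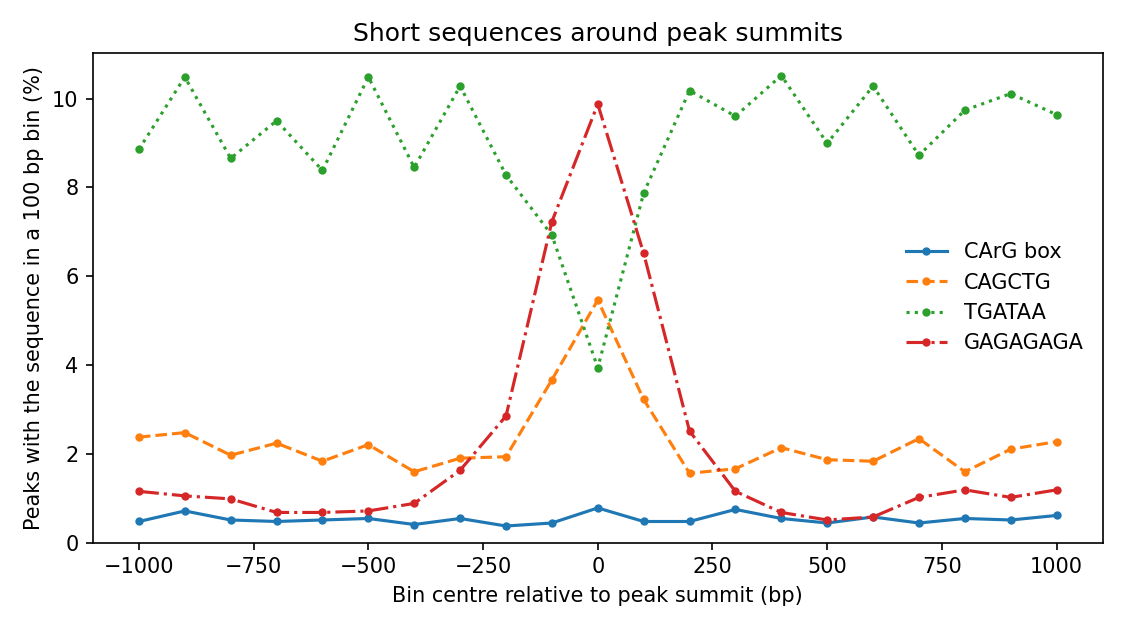
Percent of peaks with each sequence in 100 bp bins (vertical axis) by distance of the bin centre from the summit in bp (horizontal axis). GAGAGAGA rises to 9.88% of peaks in the central bin, and the CArG box stands there at 0.781%.

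The X chromosome carried 666 of 2946 peaks (22.6%, Wilson 95% interval 21.1 to 24.2) and 13.7% of protein-coding genes, a ratio of 1.65 (exact binomial test, p = 3.61e-39). Against its share of sequence length, 17.7%, the ratio was 1.28 (exact binomial test, p = 1.05e-11). Chromosome I carried 19% of peaks, 1.32 times its share of genes and 1.26 times its share of length, and chromosome III carried 16.4%, 1.24 and 1.19 times these shares. Chromosome V carried 13.3% of peaks, 0.532 times its share of genes. These values for chromosomes other than X were not tested.

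The replicates were compared through their highest ranked regions. Of the top 2946 regions of replicate 1, 82.6% overlapped a top region of replicate 2. The top regions of replicate 1 overlapped 89.3% of the nuclear IDR peaks and those of replicate 2 overlapped 90.7%, shares that are largely built in, since the IDR list is the top of the list pooled from both. Across 2920 peaks matched in both lists, Pearson's r of log2 scores was 0.76 and Spearman's rho was 0.735, both across peaks, which are not independent replicates, and over the pooled regions with the highest scores.

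The same libraries processed by the authors in ce10 gave an IDR list of 3669 regions, 1.24 times the number in ce11. X carried 22.2% of the ce10 list and 22.6% of the ce11 list. Pooled scores were 1.99 times higher in ce11 at the median and 1.99 times higher at the maximum. In each build the IDR list was exactly the set of pooled regions at or above its weakest score, 2951 of 2951 in ce11 and 3669 of 3669 in ce10.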

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

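The comparisons above left out the mitochondrial genome, and its regions were looked at only after the lists were seen. The ce11 IDR list held 5 mitochondrial regions, where none were part of the main measurement. Those with summits at 4676 and 2149 had scores of 2227 and 2123, ranks 2 and 3 of the whole list. The ranked list of replicate 1 held 12 mitochondrial regions and that of replicate 2 held 0, a difference between lists of the same length that was not tested. The ce10 lists of replicates 1 and 2 also held 12 and 0.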

How the results depend on the processing

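The alternatives were fixed before the data were examined, except keeping 1 summit per 400 bp and leaving out peaks at tRNA and snoRNA genes, chosen after seeing the data. Of 188 values with a test, 167 kept their direction and side of the threshold. Of 58 ranks of named genes, 54 stayed within the top 2946 regions, and ranks moved within it. Of 15 other values, 7 stayed within 1.5 times for counts or within the 95% interval. The sarcomere, attachment, excitation and ribosomal protein lists and the excess on X did so under each alternative run, but the sizes of the list effects moved with the rule that makes a gene bound. With the 500 bp upstream, 3000 bp upstream and nearest 5' end rules, odds ratios were 26.5, 41.2 and 52.3 for sarcomere, 9.65, 34 and 25.3 for attachment, 6.50, 53.7 and 60.2 for excitation and 22, 11.7 and 5.55 for ribosomal proteins. The order of the lists therefore depends on that rule. No paired analysis was possible because the study has 1 group. Unknown depth limits all statements about regions below the lists' cut-offs. Except for the window edge at unc-120 and the relabelling of summits by a shorter promoter, the cause of the changes below was not tested.

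Against GC-matched promoters the ratio became 2.05 for the CArG box, which gained a call, 0.746 for CACCTG, 0.994 for TGATAA, which lost its call, and 1.56 for the MEF2 type site. With 50 bp windows it was 1.21 for CACCTG, which lost its call, and 1.29 for the MEF2 type site, which with 200 bp windows gained a call at 0.51. Among the 1473 strongest peaks it was 0.727 for the CArG box, 1.22 for CACCTG and 1.24 for 5' UTRs, which both lost their calls, and 0.0559 for 3' UTRs, and 971 genes were bound. Without peaks at tRNA and snoRNA genes CACCTG lost its call at a ratio of 1.24 (exact McNemar test, adjusted p = 0.0669). Leaving out each replicate gave ratios from 1.18 to 1.89 for the CArG box, 0.458 to 0.684 for the MEF2 type site and 1.07 to 1.08 for intergenic sequence, with calls gained by the CArG box without replicate 2 and by the others without replicate 1, and odds ratios from 0.577 to 2.02 for muscle and mesoderm regulators and 0 to 1.96 for pharyngeal muscle. With a window from 500 bp upstream to 100 bp downstream the pharyngeal odds ratio was 1.26, and with one from 3000 bp upstream to the gene end the neuron odds ratio was 1.33 (adjusted p = 0.708 and 0.725, Fisher's exact test) and 3153 genes were bound. The correlation of CArG presence with score, past the threshold only before adjustment, was -0.0255 with the lower replicate score and -0.0178 with 1 mismatch allowed. With a 500 bp promoter, which relabels summits from 500 to 1000 bp upstream, the intergenic ratio gained a call at 1.14. Replicate overlaps fell to 78.5%, 77.1% and 70.4% with 50% reciprocal overlap, and to 86.1%, 87.2% and 74.4% with summits within 100 bp. The ranks of mef-2 (3155 in replicate 2), tbx-2 (2999 and 3640) and ajm-1 (3372 in replicate 1) lay below the top 2946.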

Other observations

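The searches over noncoding genes, gene name families, ubiquitous gene families and 8-mers, and the comparison of motifs between classes of peaks, were chosen after seeing the data. The predictions of the other tests were written before their results were seen.

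Transfer RNA genes carried more peaks than shifted summits did. Within 200 bp of a tRNA gene lay 199 summits, 22.6 times the mean of 1000 shifts, and 208 of 612 tRNA genes (34%, 30.3 to 37.8) had a summit there. Small nucleolar RNA genes had 82 summits (15.6 times) and small nuclear RNA genes 17 (10.3 times), each with an adjusted permutation p of 0.00257, the smallest the shifts could give. The larger group of genes annotated as ncRNA had 654 summits (22.2% of summits, 6.16 times), with the same p. Summits near piRNA genes (0.303 times) and pseudogenes (0.142 times) were rarer, with the same p. The median score was 359 at tRNA genes and 289 at other peaks. Of the tRNA peaks 89 were on X, as were 276 of the 612 tRNA genes, and without peaks at tRNA and snoRNA genes the ratio of peaks to genes on X was 1.57. Many tRNA genes have near-identical copies, so the placement of reads there is uncertain.

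Of 175 gene name families with at least 10 members, 20 were bound more often and 15 less often than other genes at an adjusted p below 0.05 by Fisher's exact test. Besides rpl and rps, those bound more often with the smallest p-values were the unc (38 of 94) and lin (19 of 47) genes. Others were vps genes of vesicle sorting (12 of 31), dnj chaperone genes (10 of 29) and cox genes of cytochrome oxidase (7 of 15). Those bound less often included the chemoreceptor families str (0 of 193) and srh (4 of 220) and the clec genes of C-type lectins (4 of 240); other chemoreceptor families, such as sri (2 of 61, Fisher's exact test, adjusted p = 0.297), missed the threshold. The 8-mers were tested against the control windows, whose GC content was lower. Of 29468 tested, AGACGCAG differed most, present only at the summit in 472 peaks and only in the control window in 32. It was rarer at tRNA peaks (5 of 199) than at other peaks (17.3%; Fisher's exact test, adjusted p = 1.04e-08), and rarer on X (9.31%) than on other chromosomes (18.3%; adjusted p = 1.85e-07).

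CArG boxes lay at 1.46% of summits, and 4 accounts of that low share were tested. Boxes displaced from the summit are argued against as the site at most peaks. The share 100 to 300 bp away was 1.93%, 0.877 times that 800 to 1000 bp away (0.617 to 1.25). These windows were not matched on GC content, so a small excess is not excluded. Sites with 1 mismatch are argued against in the same sense. They lay at 16.4% of summits and 19.8% of GC-matched promoter windows, a ratio of 0.83. Binding through them at a small share of summits would not show against so common a sequence. Base composition may hide a modest excess: the share was 1.60 times that of windows shuffled with their dinucleotides (1.16 to 2.16), an interval that spans the bound of 1.5 set beforehand. Whether an E-box factor recruits UNC-120 at muscle genes stays open, as CAGCTG lay at 1.61% of 62 muscle list peaks and 8.51% of 47 ribosomal protein peaks (Fisher's exact test, p = 0.163); a comparison with all other peaks, added after that result, gave 9.57% there (p = 0.0266, adjusted p = 0.0799). The E-box CACCTG ran the other way, at 5 of 62 muscle list peaks and 0 of 47 ribosomal protein peaks (Fisher's exact test, p = 0.0685, adjusted p = 0.206). Against all other peaks it did not differ, at 8.06% of muscle list peaks and 6.55% of the others (Fisher's exact test, p = 0.601).

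The binding of ribosomal protein promoters may reflect signal at promoters that are strongly transcribed in most cells. In 4 other ubiquitous families, of the proteasome, chaperonin, vacuolar ATPase and translation factors, 29 of 95 genes were bound (30.5%, 22.2 to 40.4), against 9.26% of all protein-coding genes. By family these were 7 of 33, 3 of 8, 5 of 20 and 14 of 34 genes. The families were chosen after the data were seen, so their share is weak evidence for this account. Their pooled share also lay below the 61.8% (50.6 to 71.9) of ribosomal protein genes, so the account may cover only part of that binding. Mitochondrial ribosome genes, outside these families, were bound in 13 of 70 cases (18.6%). The strength of transcription was not measured here. Histone genes were not bound more often, with 5 of 72 bound (6.94%; Fisher's exact test, adjusted p = 0.683), though their near-identical copies make read placement uncertain. GAGA elements are argued against as the route, since GAGAGAGA lay at 0% of 47 ribosomal protein peaks and 19.4% of 62 muscle list peaks (Fisher's exact test, adjusted p = 0.00946). Binding of UNC-120 to these promoters stays open beside this account, because profiles of input or of other GFP fusions were not used here. The same limit holds for the peaks at muscle genes, at tRNA genes and elsewhere in the list.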
